A study of Caenorhabditis elegans with 12 samples.

How the data were processed

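Whole gravid adult Caenorhabditis elegans were profiled by RNA sequencing in 4 groups of 3 libraries. Per the labels' protocols, wild-type N2 animals were kept at 25 °C for 5 generations and collected 54 to 56 h after plating of eggs (the F0 group). Part of that population was moved to 20 °C as L4 larvae and kept there for 3 generations (the F3 group, collected at 72 to 76 h), and control animals were kept in parallel at 20 °C. The remaining group carried a mutation in set-25, which encodes a histone methyltransferase that acts on lysine 9 of histone H3, and was grown at 20 °C and collected at 72 to 76 h. The labels name 3 biological replicates per group, each from 3 plates. Replicates of a group differed by more than counting noise, and by unequal amounts. The chi-square per degree of freedom over pairs of libraries was 4.13 to 4.75 within control and 5.71 to 5.88 within F0. It was 19.7 to 43.5 within F3 and 68.6 to 266 within set-25. The tests and the simulated data nevertheless used an estimate of the spread shared by the groups. RNA was extracted with TRIzol and made into strand-specific total RNA libraries with ribosomal RNA depletion and no poly(A) selection, per the labels' protocols.

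The authors deposited 1 table of 99761 features, made of 45836 genes and 53925 single repeat copies. Its values are estimated counts that need not be whole, and 22.4% of the deposited values were not whole at a tolerance of 1e-06. TopHat2 2.1.0, featureCounts 1.5.1 and DESeq2 1.8.1 are named, with no role, per the submitters' processing notes. The genome build, annotation, strand setting and treatment of reads with several matches are not given in the sources used here. Fractional values can arise when a read is divided among several places, so genes and repeat copies with near-identical sequence can share reads. The design had assumed whole-number counts, and the expected counts were rounded to whole numbers before testing. Every column of sample values was matched to a sample by its label, leaving 0 unused. Total counts per library ran from 10678819 to 35483865.

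Genes were tested with edgeR 4.0.16 (quasi-likelihood fit with robust estimation, TMM scaling, filterByExpr by group) in R 4.3.3. All 12 libraries entered 1 fit with a term per group, so that the groups shared an estimate of the spread, and 14466 genes were tested. Tests were two-sided with Benjamini-Hochberg adjustment, and genes under 0.05 were called. Comparisons were F0 against control, F3 against control, set-25 against control and F3 against F0. Log2 fold changes are given with standard errors (SE). Levels in CPM (counts scaled to library size by the TMM factors) are means ± SD over 3 libraries. Names matched the reference annotation for 44338 gene features, and chromosome positions are not printed because the build of the counted features is not stated.

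Lists of genes (37 pathway and cell type lists, with classes by biotype and chromosome region added) were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and at least 5 tested members. The lists, tests, main alternatives and naming rule were fixed before the data were examined. The naming rule took, per comparison, up to 8 called genes in each direction with the largest fold change, a gene-class name, groups that did not overlap and a mean count of at least 50 in the higher group. It added the 3 members with the smallest p from each list past its test, 1 example from other lists, genes shared between comparisons chosen the same way, and set-25, met-2, daz-1 and hrde-1 (listed as wago-9) throughout. All genes called in F3 were also considered, and those outside the rule (among them M162.12, ZC204.14, W06A11.4, R10F2.6, nhx-6, R03D7.2, F42A9.6 and the gene pair W09B7.2 and F07B7.2) were chosen after their values were seen.

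The analysis of repeats was added after the data were seen. Copies of 179 repeat families were summed per family, leaving out 2 families of ribosomal RNA, and tested by the same edgeR method on the library sizes of the gene fit, which left 157 families. Single copies were tested likewise, which left 1140. Families named in the text, and the set of MIRAGE1 copies, were chosen by their calls.

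The methods were tested on simulated data in which 200 genes were changed per group. In the data simulated for F3 against control, 47.8% of genes changed 1.5-fold, 76.1% changed 2-fold and 89.4% changed 4-fold were recovered among 13847 tested, with 6 false calls. The corresponding values were 64.2%, 76.1% and 87.9% with 9 false calls for F0, and 67.2%, 74.6% and 89.4% with 12 false calls for set-25. A list of 40 genes raised 1.3-fold was called and 0 of 20 unchanged lists were. Genes were simulated independently of one another, so this does not test lists whose genes move together. In 155 simulated families, 19 of 20 changed 2-fold were recovered with 1 false call.

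Overlaps between comparisons that shared controls were set beside 20 simulated data sets with no change. Alternatives were DESeq2 1.42.0 as test and as scaling, no filter on low counts, only the 6 libraries compared, the replicate number as a block, camera with an estimated correlation, and each library left out in turn. Added after the data were seen were fits without set-25 libraries 1 and 3 and without ribosomal RNA genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.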

Results

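The series measured RNA in gravid adults to ask which transcripts differ at 25 °C, which differ 3 generations after a return to 20 °C, and which differ in set-25 mutants. Each of the 4 groups had 3 libraries. Wild-type libraries held 28217840 to 35483865 counts and set-25 libraries 1, 2 and 3 held 22682534, 26289581 and 10678819. The first principal component held 47.5% of the variance and the next 19.4%. Ribosomal RNA made up 3.44 to 4.95% of counts in the 9 wild-type libraries, against 11.7%, 4.01% and 26.3% in set-25 libraries 1, 2 and 3. The growth protocol of the mutants names no parallel wild-type population and their libraries carry a later series of numbers, so genotype and library batch cannot be told apart.

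**Figure D1:**
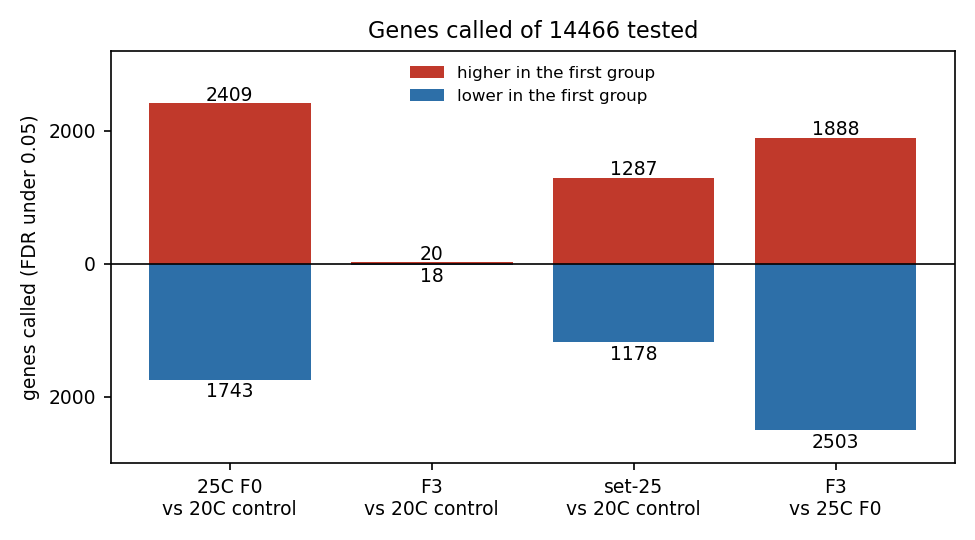
Genes called higher (upward bars) and lower (downward bars) in the first-named group of each comparison; the vertical axis is the number of genes with adjusted p under 0.05 of 14466 tested. F3 against control had 20 and 18 calls, against 2409 and 1743 for F0.

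In animals kept at 25 °C, transcripts of all major sperm protein genes tested and most other sperm genes rose, as did those of part of the heat shock, cuticle collagen and moulting genes. Part of the oocyte, intestine and mitochondrial stress genes fell. Transcripts of hsp-16.41, a small heat shock chaperone, rose most among called genes (log2 5.49, SE 0.39, adjusted p 1.69e-08 by edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 and 3), from a total of 4 counts in the controls to 212. Transcripts of asm-3, a sphingomyelinase, rose by log2 5.23 (SE 0.58), those of hmit-1.1, an inositol transporter, by 4.54 (SE 0.37), and those of lipl-2, a lipase, by 4.06 (SE 0.48). The fatty acid desaturase gene fat-7 fell by 3.67 on the log2 scale (SE 0.19), the C-type lectin gene clec-169 by 2.25 (SE 0.32) and the cytochrome P450 gene cyp-13A4 by 1.83 (SE 0.24). In all, 2409 genes were higher and 1743 lower, of which 898 and 145 by at least 2-fold. Groups did not overlap for 50.4% of genes, where chance gives 10%. The F0 animals were also collected at fewer hours than the controls, so temperature and time since plating were not separated.

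Of 25 heat shock response genes tested, 13 were higher and 4 lower (13 and 7 adjusted over the list alone), and 8 were not called (camera adjusted p = 0.13 with an estimated correlation). They included hsp-16.48 (log2 2.20, SE 0.12) and hsp-16.11 (1.94, SE 0.12), whose counts nearly equal those of hsp-16.49 and hsp-16.1, so the values of these pairs are uncertain. Every one of 31 major sperm protein genes tested was higher, also adjusted over the list alone, with a median log2 of 2.96 (camera adjusted p = 0.767 with an estimated correlation). Among the other sperm genes 36 of 42 were higher (36 adjusted over the list alone), including ssp-31 (4.29, SE 0.50) and spe-11 (3.81, SE 0.46), with a camera adjusted p = 0.524 with an estimated correlation. The share of all counts on major sperm protein genes was 0.0219 ± 0.00411% in F0 and 0.00279 ± 0.0019% in controls (SD, n = 3, exact permutation p 0.1, two-sided, the smallest that 3 against 3 libraries allow). Many of these genes are near-identical, and their single values are uncertain. Collagen genes were higher in 53 and lower in 3 of 126 (55 and 5 adjusted over the list alone), for example col-180 (2.27, SE 0.24), col-147 (2.03, SE 0.18) and col-13 (1.73, SE 0.15), with a camera adjusted p = 0.58 with an estimated correlation. Among moulting genes 9 of 26 were higher (9 adjusted over the list alone), including the cuticle genes noah-1 (1.06, SE 0.12) and noah-2 (1.25, SE 0.13), with a camera adjusted p = 0.627 with an estimated correlation.

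Of 29 oocyte genes 15 were lower (20 adjusted over the list alone), including gna-2 (-0.41, SE 0.04) and egg-3 (-0.25, SE 0.03), with a camera adjusted p = 0.767 with an estimated correlation. Intestinal genes were lower in 12 and higher in 2 of 26 (13 and 3 adjusted over the list alone), among them cpr-5 (-0.76, SE 0.08) and the peptide transporter gene pept-1 (-0.58, SE 0.05), with a camera adjusted p = 0.521 with an estimated correlation. Mitochondrial stress genes were lower in 8 of 14 (8 adjusted over the list alone), including the chaperone gene hsp-6 (-0.45, SE 0.05), with a camera adjusted p = 0.335 with an estimated correlation. Small RNA pathway genes were lower in 18 and higher in 3 of 46 (22 and 3 adjusted over the list alone), with mut-7 at -0.27 (SE 0.04) and a camera adjusted p = 0.58 with an estimated correlation. The MATH and BTB domain genes were higher in 30 and lower in 8 of 79 (35 and 10 adjusted over the list alone), with bath-13 at 2.48 (SE 0.22) and a camera adjusted p = 0.319 with an estimated correlation. Among lists that did not pass the list test, F-box genes were higher in 57 and lower in 15 of 260 (56 and 15 adjusted over the list alone), C-type lectin genes in 31 and 20 of 100 (33 and 24), and antimicrobial peptide and lysozyme genes in 25 and 12 of 66 (26 and 13). The list test with a preset correlation called 13 lists, each of which lost its call with an estimated correlation. With no low-count filter it called 20. Transcripts of set-25 itself (-0.34, SE 0.07) and met-2 (-0.18, SE 0.04), both histone methyltransferase genes, were lower, as were those of the germ cell gene daz-1 (-0.23, SE 0.04), while wago-9 (-0.06, SE 0.06) was not called, except with only the 6 libraries compared.

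**Figure D2:**
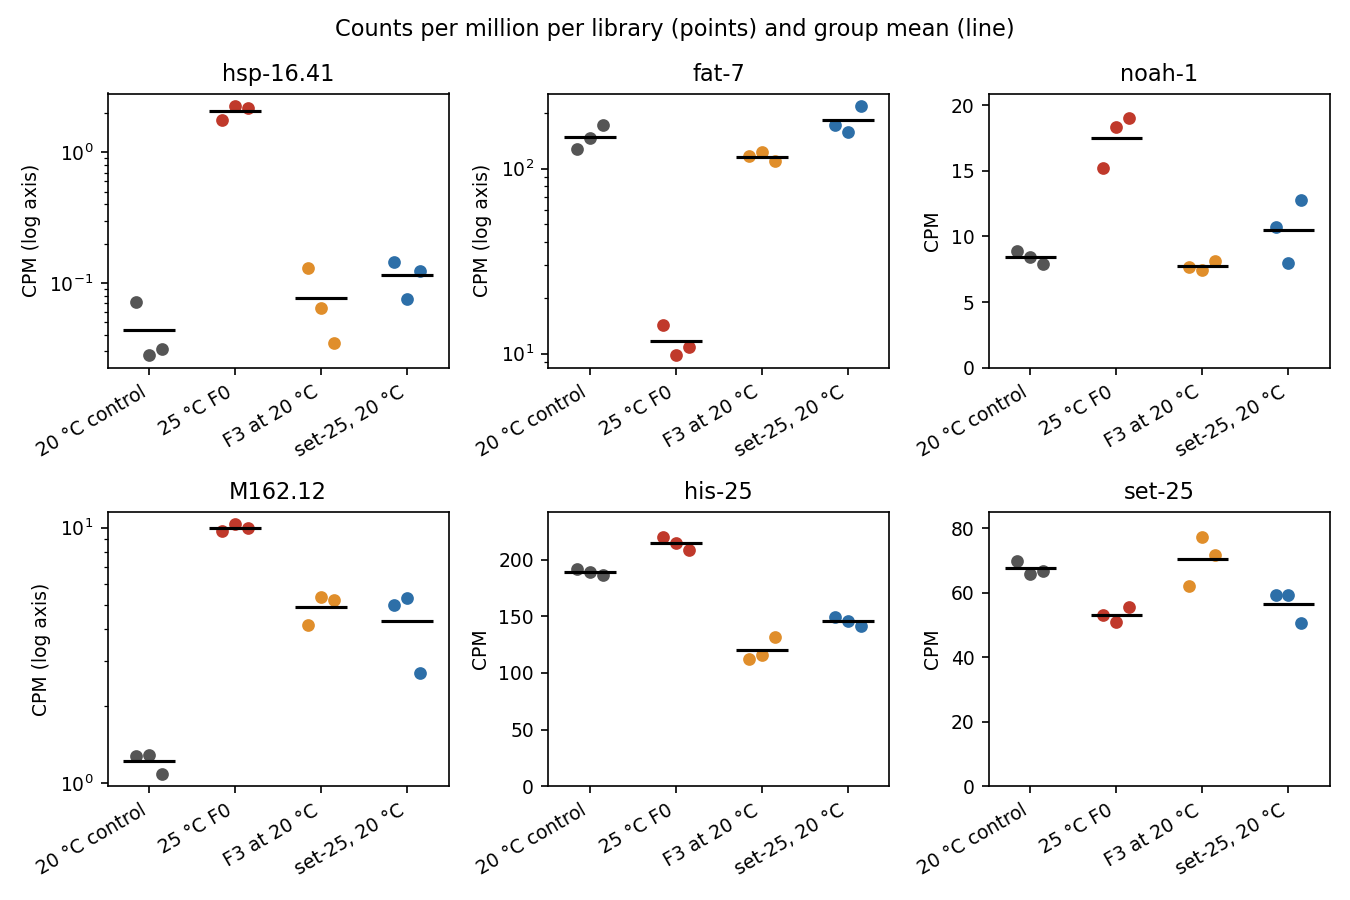
Level in CPM (counts scaled to library size) for 6 genes in the 12 libraries; points are libraries and lines are group means, with a log axis for hsp-16.41, fat-7 and M162.12. The M162.12 means are 1.22 in control and 4.91 in F3.

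At 3 generations after the return to 20 °C, few genes differed from control. Transcripts of the pseudogene M162.12 (log2 2.00, SE 0.18, adjusted p 1.68e-05 by edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 and 3) and the pseudogene W06A11.4 (1.54, SE 0.17) were higher, as were those of ZC204.14 (1.40, SE 0.15) and of nhx-6, a sodium/proton exchanger gene (3.44, SE 0.50, from 8 to 86 counts in total). The synaptotagmin gene snt-2 (0.67, SE 0.09), the homeobox gene ceh-20 (0.64, SE 0.10), R10F2.6 (0.84, SE 0.11), M04F3.3 (0.73, SE 0.11) and F30B5.4 (0.54, SE 0.06) were also higher. Lower were R03D7.2 (-0.97, SE 0.11), F42A9.6 (-0.73, SE 0.08), the F-box gene fbxa-192 (-0.80, SE 0.11) and histone genes. In all 20 genes were higher and 18 lower, and 731 had an unadjusted p under 0.05. Groups did not overlap for 9.21% of genes, where chance gives 10%.

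Of 79 histone genes 10 were lower in F3 (12 lower and 1 higher adjusted over the list alone), led by his-25 (-0.66, SE 0.05), his-26 (-0.57, SE 0.07) and his-42 (-0.43, SE 0.06). Counts of his-26 nearly equal those of his-10, and those of his-9 and his-13 and of his-44 and his-11 are as close, so these values are uncertain. In F0, 13 of the 79 histone genes were higher and 13 lower (13 and 13 adjusted over the list alone, median log2 -0.03, camera adjusted p 0.378 with the preset correlation). Among the histone genes lower in F3, 8 were higher in F0 and different between the generations, such as his-15 (0.41 in F0, -0.45 in F3). The calls of his-15 (-0.40 and -0.41), his-9 (-0.42 and -0.45), his-11 (-0.41 and -0.41), his-13 (-0.44 and -0.46) and his-44 (-0.41 and -0.41) in F3 were lost without F3 replicates 1 and 2. That of his-10 was lost without control replicate 1 (-0.55) and F3 replicate 2 (-0.56), and that of his-43 without control replicates 1 (-0.58) and 3 (-0.53) and F3 replicate 2 (-0.58). With only the 6 libraries compared, his-25 and his-42 were still called and the other 8 histone genes, his-26 among them, were not. All histone genes together made up 2.75 ± 0.276% of counts in F3 and 2.97 ± 0.041% in control (exact permutation p 0.4). F3 libraries 1, 2 and 3 held 2.47%, 2.76% and 3.02%. Collagen genes had 0 of 126 called by edgeR and 0 adjusted over the list alone, 1 by DESeq2 and 40 under an unadjusted p of 0.05, with a median log2 of -0.31. Ribosomal protein genes had 0 of 80 called by edgeR (0 adjusted over the list alone) or DESeq2 and 14 under an unadjusted p of 0.05. The list test called 7 lists with the preset correlation, each of which lost its call with an estimated correlation (histone and collagen adjusted p = 0.404, ribosomal protein adjusted p = 0.971 by camera with an estimated correlation). The ribosomal protein list lost its call without F3 replicate 1 (camera adjusted p = 0.145), and the count of lists was 12 without F3 replicate 1 and 14 without F3 replicate 3. Heat shock genes had 0 of 25 called by edgeR (0 adjusted over the list alone) or DESeq2 and 2 under an unadjusted p of 0.05, and major sperm protein genes had 0 of 31 by each of these. In F3, hsp-16.11 was at -0.35 (SE 0.14, adjusted p 0.893 by edgeR with Benjamini-Hochberg adjustment). Transcripts of set-25 (0.06, SE 0.07) and wago-9 (-0.02, SE 0.06) were not called.

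The F3 count depended on single libraries and on the low-count filter. It was 104 without F3 replicate 3, 20 without F3 replicate 2, 24 without F3 replicate 1 and 23 without control replicate 1, 15 with only the 6 libraries compared, and 96 with no filter, where 26920 genes were tested. Of the 38 genes, 9 higher and 6 lower, all named above, were called in each of the 6 fits without 1 library.

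Between F3 and F0, 1888 genes were higher in F3 and 2503 lower. Transcripts of hsp-16.41 fell by 4.66 on the log2 scale (SE 0.36, adjusted p 4.14e-08 by edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 and 3), those of asm-3 by 5.89 (SE 0.64) and those of ilys-2, a lysozyme gene, by 4.15 (SE 0.48). Also lower were hmit-1.1 (-3.94, SE 0.35), sdz-6 (-4.02, SE 0.34) and acs-18 (-3.90, SE 0.46). Transcripts of fat-7 rose by 3.31 (SE 0.19), those of cyp-29A4 by 1.90 (SE 0.17), those of clec-70 by 1.90 (SE 0.16) and those of cyp-13A5 by 1.81 (SE 0.28). Transcripts of set-25 (0.40, SE 0.07), met-2 (0.20, SE 0.04) and daz-1 (0.33, SE 0.04) were higher in F3, and those of the chromodomain gene cec-4 lower (-0.60, SE 0.06). In the list of H3K9 methylation and heterochromatin genes, 11 of 32 were higher and 1 lower (12 and 1 adjusted over the list alone). Its camera adjusted p = 0.426 with an estimated correlation. Major sperm protein genes were lower in 31 of 31, also adjusted over the list alone (camera adjusted p = 0.741 with an estimated correlation). Collagen genes were lower in 78 of 126 with 4 higher (85 and 4 adjusted over the list alone, camera adjusted p = 0.376 with an estimated correlation). Heat shock genes were lower in 13 of 25 with 4 higher (13 and 5 adjusted over the list alone). Oocyte genes were higher in 17 of 29 (18 adjusted over the list alone), among them nos-2 (0.24, SE 0.04), with a camera adjusted p = 0.741 with an estimated correlation. Vitellogenin genes, which encode yolk proteins, were higher in 5 of 6 (5 adjusted over the list alone, camera adjusted p = 0.741 with an estimated correlation). Of the 14 lists called, 1, heat shock, held with an estimated correlation (adjusted p = 0.0415 by camera with an estimated correlation). Leaving out F3 replicate 1 gave 22 lists.

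In set-25 mutants the transcript of set-25 was slightly lower, at 50.7 to 59.3 CPM against 65.9 to 69.8 in controls (log2 -0.24, SE 0.07, adjusted p 0.0328 by edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 and 3). The lesion of the allele is not given in the sources used here, so this level does not check the labels. The call was lost in 5 of 6 fits without 1 library: without control replicates 1 (-0.23), 2 (-0.27) and 3 (-0.26) and without set-25 replicates 1 (-0.27) and 3 (-0.19). It was also lost without set-25 libraries 1 and 3 together (-0.19). The called gene furthest below control was lov-1, a polycystin gene, with 1 count in the 3 mutant libraries and 460 in the controls, a ratio of 0.00377 after scaling to library size (95% exact binomial interval 9.54e-05 to 0.0211, counting error only). Sequence differences between the mutant strain and N2 other than the set-25 mutation were not analysed here, so this value is not tied to set-25. The F-box gene fbxa-136 (3.27, SE 0.31), math-45 (3.17, SE 0.25), bath-13 (2.58, SE 0.23) and dod-24 (2.09, SE 0.26) were higher, and ram-2, of the epidermis list, (-2.52, SE 0.17), grl-17 (-2.75, SE 0.29), C33G8.3 (-2.51, SE 0.42), ptr-15 (-1.96, SE 0.32) and the collagen gene col-104 (-2.73, SE 0.56, not called without set-25 libraries 1 and 3) lower. In all 1287 genes were higher and 1178 lower, 184 and 127 by at least 2-fold. Groups did not overlap for 39.7% of genes, where chance gives 10%. The count was 1595 without control replicate 3 and 1613 without set-25 replicate 1.

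MATH and BTB domain genes were higher in 20 and lower in 1 of 79 (22 and 2 adjusted over the list alone), and F-box genes in 28 and 3 of 260 (25 and 3), with camera adjusted p = 0.182 and adjusted p = 0.488 with an estimated correlation. Meiotic germline genes were higher in 8 and lower in 1 of 33 (8 and 1 adjusted over the list alone), including daz-1 (0.45, SE 0.04), gld-2 (0.51, SE 0.05) and gld-1 (0.35, SE 0.05), which encode regulators of germ cell RNA (camera adjusted p = 0.678 with an estimated correlation). Vitellogenin genes were higher in 5 of 6 (5 adjusted over the list alone), among them vit-5 (0.57, SE 0.08), with a camera adjusted p = 0.612 with an estimated correlation. Collagen genes were lower in 40 and higher in 1 of 126 (52 and 1 adjusted over the list alone), for example col-13 (-1.36, SE 0.20), with a camera adjusted p = 0.539 with an estimated correlation. Ribosomal protein genes were lower in 33 of 80 (58 adjusted over the list alone), with a median log2 of -0.22, and histone genes in 16 of 79 with 2 higher (16 and 2), including his-25 (-0.38, SE 0.05). Their camera adjusted p = 0.79 and adjusted p = 0.858 with an estimated correlation. Among biotype classes, 3 of 44 snRNA and 3 of 87 snoRNA genes were lower and 0 higher (0 adjusted over each list alone). Medians of these classes were log2 -0.68 and -0.42 (camera adjusted p = 0.797 and adjusted p = 0.84 with an estimated correlation). Ribosomal RNA was highest in set-25 libraries 1 and 3; with those left out, a choice made after seeing the data, 1 ribosomal protein gene was lower (median -0.19) and 15 of 131 collagen genes were (median -0.77). The count of genes was then 742, of which 697 were among the 2465. The list test called 13 lists, each of which lost its call with an estimated correlation.

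Genes called against control in more than 1 group were compared. Between F0 and F3, 18 genes were higher in both and 5 lower in both, where independent lists give 3.33 and 2.17 and simulated unchanged groups gave 0.05 and 0, and 8 went in opposite directions (independent 5.41). Between F0 and set-25 these numbers were 321 and 240 (independent 214 and 142, simulated 0 and 0.05), and 296 genes went in opposite directions (independent 351). Between F3 and set-25 they were 10 and 4 (independent 1.78 and 1.47, simulated 0 and 0), with 5 in opposite directions (independent 3.23). Across genes, which are not independent replicates, fold changes correlated at r = 0.09, 0.12 and 0.35 in these pairs, against 0.5, 0.45 and 0.45 in simulations. The covariance differed from the simulated one by -0.00741, 0.0192 and 0.0247. The simulated groups held no changed genes, so few or no calls were to be expected there. Their overlaps of calls therefore cannot show how much shared controls add. By unadjusted p, 270 genes went the same way in F0 and F3, against a simulated mean of 131. In F3 and set-25 there were 294 against 118. In F0 and set-25 there were 1263, with a simulated mean under 131. Genes with an unadjusted p under 0.05 numbered 5714 in F0, 731 in F3 and 4457 in set-25. Many changed genes raise such overlaps even between independent lists, and the simulated groups held no changed genes. The simulated means therefore cannot show how much shared controls add to these overlaps either. The overlap of independent lists was not computed for unadjusted p. The comparisons share 3 control libraries, which cannot be split, and part of the excess over independent lists may come from them. The simulated groups shared their controls in the same way. Leaving out F3 replicate 3 gave 44 genes lower in both F0 and F3 and 58 lower in both F3 and set-25. The genes higher in both F0 and F3 fell to 11 without control replicate 1 and 10 without F3 replicate 2, and those lower to 1 without control replicate 1, 2 without F3 replicate 1 or 2, and 3 without control replicate 2 or F0 replicate 2 or 3. The genes higher in both F0 and set-25 were 184, 210 and 171 without control replicates 1, 2 and 3 and 198 without set-25 replicate 1, and those lower were 149 and 130 without control replicates 1 and 3 and 148 without set-25 replicate 1. The genes higher in both F3 and set-25 were 5 without control replicate 1 or 3 or F3 replicate 2 and 6 without F3 replicate 1. Those lower were 2 without control replicate 1, F3 replicate 2 or set-25 replicate 1 or 2, and 13 without control replicate 3. Without set-25 libraries 1 and 3 the genes higher and lower in both F0 and set-25 were 102 and 61, and those lower in both F3 and set-25 were 2. With no low-count filter 31 genes were higher and 19 lower in both F0 and F3, 461 lower in both F0 and set-25, and 17 higher and 32 lower in both F3 and set-25, while DESeq2 gave 9 lower in both F3 and set-25.

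Higher in F0, F3 and set-25 alike were 10 genes: bath-12, bath-13, ZC204.14, W06A11.4, M162.12, fbxa-136, F56D6.16, C18H2.2, K06B9.4 and K03D7.1. By DESeq2 11 genes were higher in all 3, and 70 at an unadjusted p under 0.05 in each. Lower in all 3 were 0 by edgeR, 1 by DESeq2 and 49 at an unadjusted p under 0.05 in each. In F3, bath-12 was at 0.46 (SE 0.09), against 1.31 (SE 0.09) in F0 and 1.31 (SE 0.09) in set-25. Of the 10, M162.12, ZC204.14 and W06A11.4 were called in F3 in each fit without 1 library. The call of bath-12 was lost without control replicates 1 (0.49), 2 (0.42) and 3 (0.46) and F3 replicates 1 (0.44) and 2 (0.46), and that of K03D7.1 without the same 5 libraries (0.34, 0.35, 0.33, 0.34 and 0.31). The call of bath-13 was lost without control replicates 1 (1.13) and 3 (1.25) and F3 replicates 1 (1.23) and 3 (1.16). Those of fbxa-136 and F56D6.16 were lost without control replicates 2 (1.71 and 1.13) and 3 (1.91 and 1.45) and F3 replicates 1 (1.88 and 1.29) and 2 (1.92 and 1.43). Those of C18H2.2 and K06B9.4 were lost without control replicate 1 (0.39 and 0.36) and F3 replicate 2 (0.41 and 0.37). With only the 6 libraries compared, the F3 calls of bath-12, bath-13, fbxa-136, F56D6.16, K06B9.4 and K03D7.1 were lost and those of the other 4 were kept.

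Repeat families were examined after the data were seen. MIRAGE1, a DNA transposon family, was higher than control in F0 (log2 2.73, SE 0.21), F3 (1.24, SE 0.21) and set-25 (2.96, SE 0.21), and 10 of its 15 tested copies were called higher in all 3. Another copy, MIRAGE1_62, was called lower in F0 (-0.63, SE 0.12) and in F3 (-0.51, SE 0.12). The summed level of the 10 copies was 1.79 ± 0.432 CPM in control, 106 ± 4.98 in F0, 29.6 ± 7.71 in F3 and 116 ± 30.1 in set-25 (SD, n = 3). That is log2 5.91 (SE 0.32), 4.07 (SE 0.33) and 6.03 (SE 0.32), with F3 at -1.84 (SE 0.23) against F0. Of the 10, MIRAGE1_44 was instead higher in F3 than in F0 (1.39, SE 0.30), and MIRAGE1_43 was at 1.18 (SE 0.33) and not called. The 10 copies were chosen by their calls, which can overstate a change. The 6 copies with the largest rise in F0 had means of 15.5 to 17.7 CPM there. Their lowest correlation with one another across libraries was 0.999. Reads may therefore be divided among them, and the copies need not be separate signals. CEMUDR1, another DNA transposon family, was at 64.8 ± 1.89 CPM in control, 111 ± 4.03 in F0, 107 ± 2.86 in F3 and 128.5 ± 12.7 in set-25. The retrotransposon family CER1 was lower in F0 (-1.35, SE 0.06), at 141 against 360 CPM, and rested on 1 tested copy. CER9 elements were lower in F0 (-1.64, SE 0.17) and higher in set-25 (2.24, SE 0.14). Of 157 families, 11 were higher and 17 lower in F0, 3 and 2 in F3, and 26 and 4 in set-25, by edgeR with Benjamini-Hochberg adjustment. Without F3 replicate 2 the F3 count was 8, and the set-25 count was 19 without control replicate 2, 17 without control replicate 3 and 8 without set-25 libraries 1 and 3, which held most ribosomal RNA.

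**Figure D3:**
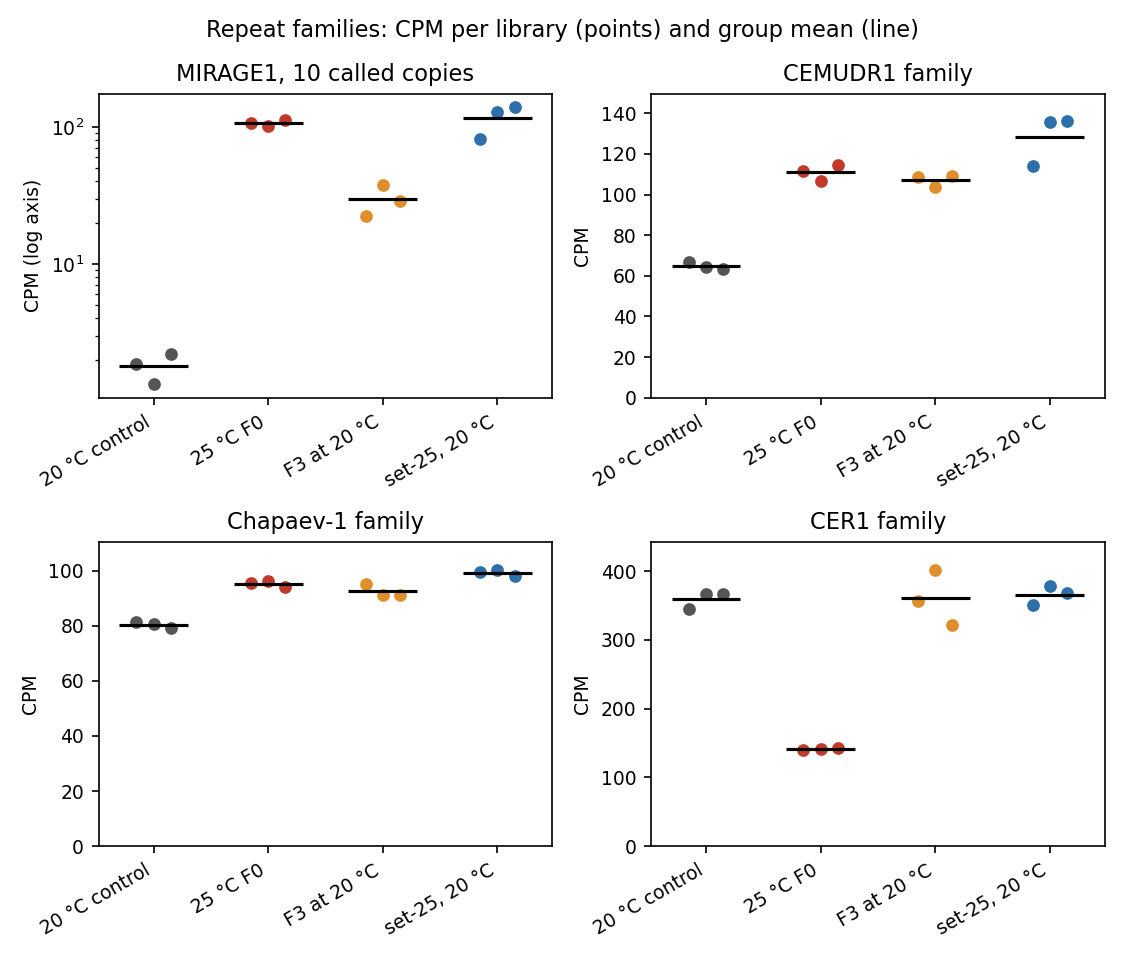
Level in CPM (counts scaled to library size) of 3 repeat families and of 10 MIRAGE1 copies chosen by their calls, in the 12 libraries; points are libraries and lines are group means, with a log axis for MIRAGE1. The MIRAGE1 copies average 1.79 in control and 29.6 in F3.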

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

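All tests of explanations in this part, the counts over other splits included, were chosen after the result was seen. The share of counts on ribosomal RNA repeat copies was 4.17% in set-25 library 1 and 11.9% in set-25 library 3, above the highest control library (0.709%), a signal outside the tested families. A set of 8 histone genes (his-9, his-11, his-13, his-15, his-25, his-42, his-43 and his-44) were higher in F0 and lower in F3 than in control, and all differed between F3 and F0 by edgeR. Of all 79 histone genes 13 were higher and 13 lower in F0, and counts of his-9 and his-13 and of his-44 and his-11 are nearly equal, so the 8 are not 8 separate signals. The F3 calls of 6 of them were lost with only the 6 libraries compared and in fits without 1 library: his-9 (-0.42, -0.45), his-11 (-0.41, -0.41), his-13 (-0.44, -0.46), his-15 (-0.40, -0.41) and his-44 (-0.41, -0.41) without F3 replicates 1 and 2, and his-43 without control replicates 1 (-0.58) and 3 (-0.53) and F3 replicate 2 (-0.58).

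In set-25, 33 of 80 ribosomal protein genes and 40 of 126 collagen genes were called lower and 0 and 1 higher (camera adjusted p = 0.79 and adjusted p = 0.539 with an estimated correlation), and set-25 libraries 1 and 3 held most ribosomal RNA. With ribosomal RNA genes removed before scaling, 33 and 39 were called lower and the median log2 was -0.216 and -0.583, against -0.221 and -0.585 with them, so their weight in the scaling moved the medians little. With libraries 1 and 3 left out the medians were -0.188 and -0.773, the collagen value being further from 0, but these rest on 1 library, which excludes nothing, and calls went from 33 to 1 for ribosomal protein and from 40 to 15 for collagen genes. Another effect of carry-over on these libraries therefore stays open. A library batch and the mutation itself stay open too, because the labels name no wild-type population grown beside the mutants.

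MIRAGE1, CEMUDR1 and Chapaev-1 counts were higher in F0, F3 and set-25. Low control libraries by chance stay open: in 3 of 3 families the gap from the highest control to the lowest other library exceeded the fold between controls (1.62 against 1.5 for MIRAGE1, 1.55 against 1.06 for CEMUDR1, 1.12 against 1.03 for Chapaev-1), and the 10 MIRAGE1 copies summed to 1.33 to 2.19 CPM in controls and 22.4 to 139 in the others. These families and copies were chosen by their calls against the same controls, which nearly fixes that outcome. Without set-25 libraries 1 and 3, with the most ribosomal RNA, 3 of 3 families were called, again from 1 library. Reads shared between near-identical copies may set where the rise is placed, since the 6 leading MIRAGE1 copies lay within 1.15-fold of one another in F0, and temperature, descent and the mutation remain untested as biological causes.

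In F0, 31 of 31 major sperm protein, 53 of 126 collagen and 9 of 26 moulting genes were called higher and 3 collagen genes lower (camera adjusted p = 0.767, adjusted p = 0.58 and adjusted p = 0.627 with an estimated correlation). Animals of another stage at collection could give this, and across the 6 wild-type libraries at 20 °C the list means of major sperm protein and collagen genes had Pearson r = 0.55 (exact permutation p 0.237, adjusted p 0.588 by Benjamini-Hochberg over 3 relations) and Spearman rho = 0.43 (exact permutation p 0.419), with r = 0.44 without the 2 libraries farthest from the median. With moulting genes r was 0.48 (exact permutation p 0.392, adjusted 0.588; rho 0.6, p 0.242; r = 0.5 without those 2 libraries) and with oocyte genes 0.1 (exact permutation p 0.857, adjusted 0.857; rho 0.26, p 0.658; r = 0.95 without them), none of which decides it. Such a difference cannot be told apart from temperature here, because hours of growth went with temperature. Without control replicate 2, 75.8% (69 of 91) of the genes called higher, each counted once, were still called. This was under a bound of 80% set after the result was seen, so by that count a result decided by 1 library stays open. The other fits without 1 library kept 82.4 to 94.5%. Without control replicate 2 all 91 were still higher, with a median log2 of 1.70 against 1.73. The 91 were chosen by their calls in these same libraries, which nearly fixes that outcome, so it decides nothing. The 3 lists, fixed beforehand, each kept their call with the preset correlation in 6 of 6 fits without 1 library. Major sperm protein genes held 0.0193 to 0.0267% of counts in the F0 libraries and 0.000718 to 0.00445% in the controls. For these genes that argues against a result decided by 1 library. For collagen and moulting genes such a result stays open.

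The 6 libraries of a comparison can be split in 10 ways, the real one included, so the share of splits as large is never under 0.1. The real split gave 4152 genes for F0, 38 for F3, 2465 for set-25 and 4391 for F3 against F0, and the highest other split 0, 1, 0 and 1; in each, 1 of 10 splits was as large. For repeat families the real counts were 28, 5, 30 and 19 and the highest other 0 throughout, with 1 of 10 as large. Each other split mixes libraries of both groups on each side. A real difference then widens the spread within the groups and leaves few genes or families to call. These counts of genes and families therefore decide nothing about chance. For gene lists the real counts were 13, 7, 13 and 14 and the highest other 20, 27, 13 and 29, with 5, 10, 4 and 8 of 10 splits as large. Splits that call several times the real number of lists, as for F3, could come from a structure of the samples or from the preset correlation. Neither was tested. The 7 lists of the real F3 split lost their call with an estimated correlation, and the other splits were not run with it.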

How the results depend on the processing

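Fits without set-25 libraries 1 and 3, without ribosomal RNA genes, and all fits of repeat families were chosen after the data were seen. Another scaling moved the median of all genes by at most 0.011 in log2. For called gene values, 230 of 233 kept direction and call with DESeq2 scaling, 230 with the DESeq2 test, 231 with no filter on low counts, 204 with only the 6 libraries compared, 228 of 231 without ribosomal RNA genes, 41 of 64 without set-25 libraries 1 and 3, and 1256 of 1398 across fits without 1 library; the cause was not tested except that fewer libraries were fitted. The gene values cover only genes taken by the naming rule or called in F3, not all called genes. Called values of the repeat families picked after the data were seen kept their call in 156 of 156 fits without 1 library. Over all tested families the set-25 count went from 30 to 17 without control replicate 3.

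With no filter, where more genes were tested, the F3 count was 96, and with only the 6 libraries it was 15. The cause of either change was not tested. Genes shared with no filter were 31 higher and 19 lower for F0 and F3, 461 lower for F0 and set-25, and 17 higher and 32 lower for F3 and set-25 (9 lower with the DESeq2 test), and F0 lists were 20. Without set-25 libraries 1 and 3 the set-25 counts were 742 genes and 8 families, overlaps with F0 were 102 and 61, genes lower with F3 were 2, and the set-25 transcript was at -0.19 (adjusted p 0.314 by edgeR, over alternatives 1.83e-05 to 0.314); fewer samples were fitted. With an estimated correlation the lists called were 0, 0, 0 and 1 for F0, F3, set-25 and F3 against F0.

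Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.04, -0.10 and -0.21 for F3 and control, and not every sample correlated best with its own number. With the number as a block the gene counts were 3861, 35, 2220 and 4123, the set-25 transcript stayed at -0.24 (adjusted p 0.0587 by edgeR), and 223 of 233 called gene values kept their call, those of bath-12 and K03D7.1 in F3 not among them.

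Leaving out 1 library gave 3236 to 3386 genes for F0, 20 to 104 for F3, 1595 to 1918 for set-25 and 3450 to 4851 for F3 against F0. Lists ran from 10 to 19, 6 to 14, 12 to 15 and 14 to 22, and families from 24 to 27, 5 to 8, 17 to 27 and 16 to 22. Shared genes ran from 10 to 18 higher and 1 to 44 lower for F0 and F3, 171 to 257 and 130 to 225 for F0 and set-25, and 5 to 13 and 2 to 58 for F3 and set-25. The set-25 transcript ran from -0.385 to -0.323 in F0, -0.289 to -0.187 in set-25, 0.339 to 0.5 in F3 against F0 and -0.016 to 0.144 in F3, where it was below 0 without F3 replicate 2. Other results turned direction too, of which the snoRNA list alone had been called. In fits without 1 library wago-9 ran from -0.072 to 0.05 in F3 and -0.015 to 0.024 in set-25 (-0.022 with no filter), CER1 from -0.084 to 0.078 and -0.017 to 0.051, and CER16-2 in F3 from -0.196 to 0.038, while CER10 in set-25 was at 0.009 without libraries 1 and 3. The snoRNA list in F3 ran from a camera adjusted p of 5.76e-13 without F3 replicate 3 to 0.974 without F3 replicate 2, where its direction turned. The cause was not tested.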

Other observations

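The repeat tests and the test of neighbouring repeats in this part were chosen after the result was seen. Single repeat copies were tested beside the families. Of 1140 copies, 42 were higher and 45 lower in F0, 18 and 5 in F3, and 63 and 9 in set-25. Copies of the transposon family Tc1A were higher in 10 of 14 tested in F0 and in 6 in set-25. Of 10 tested CER9 internal copies, 8 were lower in F0 and 9 higher in set-25. The genes W09B7.2 and F07B7.2 have nearly equal counts, so their values are uncertain; both were at -3.26 in F0, 2.98 in set-25 and -1.16 in F3. The F3 call of W09B7.2 was lost without control replicates 1 (-1.0) and 2 (-1.11) and F3 replicates 1 (-1.18) and 2 (-1.08), and with only the 6 libraries compared.

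Mitochondrially encoded genes were higher in 7 of 14 in set-25 (11 adjusted over the list alone, camera adjusted p = 0.709 with an estimated correlation). They made up 5.27 ± 0.4% of all counts against 4.20 ± 0.195% in control (exact permutation p 0.1, the smallest that 3 against 3 allow). In F0, 5 were higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.846 with an estimated correlation). Their share in F0 was 4.94 ± 0.217% (exact permutation p 0.1). In set-25 libraries 1, 2 and 3 it was 5.15%, 5.72% and 4.95%, and F3 library 1 held 5.80%. Libraries 1 and 3 of set-25 also held the most ribosomal RNA. Cytochrome P450 genes were higher in 11 and lower in 2 of 64 in set-25 (11 and 3 adjusted over the list alone, camera adjusted p = 0.797 with an estimated correlation, and 0.0689 with the preset correlation without set-25 replicate 2) and higher in 9 and lower in 11 in F0 (9 and 11).

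Genes higher in F3 may lie beside copies of a repeat family. This was noticed among these same genes and then tested on them. Of the 20 genes, 4 (M162.12, ZC204.14, W06A11.4 and M04F3.3) had a Chapaev-2 copy within 3 table positions, against 0.415% of all tested genes (Fisher's exact test p 1.23e-06, adjusted p 0.000193 over 157 families by Benjamini-Hochberg). Table order followed genome order for 99.3% of 44321 neighbouring pairs of annotated genes. The places of repeat copies in the table were not checked. Since the pattern was seen in these genes first, this p is no independent support. Of the genes at least 2-fold higher in set-25, 5 had a Chapaev-2 copy as near (adjusted p 0.0256 over 157 families), but 3 of these are among the 20. Without the 20 genes, 2 of 177 genes at least 2-fold higher in set-25 had such a copy (1.13% against 0.388% of all, Fisher's exact test p 0.15, adjusted p 0.3 over 2 sets by Benjamini-Hochberg) and 4 of 888 in F0 (0.45%, p 0.777, adjusted p 0.777). The hypothesis rests on 4 genes and was not borne out in these other genes, which are few in set-25.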
